A study of Homo sapiens with 22 samples.

How the data were processed

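Gene expression was measured in 3 cell types: the human breast cancer lines MDA-MB-436 and HCC1954, and purchased normal human mammary epithelial cells (HMEC). The 22 samples cover 4 array types. Each cell type was hybridised to 2 arrays of each of the 3 Affymetrix types U95A, U133A and U133B, and each line to 2 two-colour arrays against HMEC. Per the labels, total RNA was extracted with TRIzol LS and RNeasy columns, and Affymetrix targets were made from about 7 ug of it. The two-colour titles put the line in Cy3 and HMEC in Cy5, with no dye swap.

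The deposited Affymetrix values are log2 signals per probe set with 2 decimals and no detection calls. The 6 arrays of each type already had nearly equal quantiles, so they were used as deposited; linear signals had been allowed for in the plan, and the log step was left out. The probe set summary and the scaling between arrays are not given in the sources used here. The deposited two-colour values are log2 of ratios that are whole hundredths, to within 2% of a hundredth, between 0.01 and 100. Which channel is on top is not stated. The values correlated positively with the Affymetrix folds of line over HMEC (r = 0.772 and 0.794 across genes with U133A, and -0.77 and -0.79 with the sign turned), and so were read as line over HMEC. Each two-colour array was centred on its median and the spots of a gene were averaged. Replicate 1 of MDA-MB-436 and replicate 1 of HCC1954 had nearly the same SD of log2 ratios (both 0.926), against 1.15 and 0.976 for the replicates 2, so a rescaling before deposit is not excluded, and its effect on two-colour sizes and spreads was not tested.

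Labels conflict in 4 samples: both HCC1954 two-colour samples name MDA-MB-436 as their source, and both MDA-MB-436 U133B samples carry the description of HMEC. Groups were taken from the titles. On the 100 probe sets that U133A and U133B share, the fold of MDA-MB-436 over HMEC correlated at r = 0.990 between the array types, as the titles require. ERBB2 was 4.92 higher on the log2 scale in the two-colour arrays titled HCC1954.

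Probe sets were named from the array tables, with current symbols taken by gene ID from the RefSeq gene table of assembly GRCh38.p14. One symbol was found for 10961 of 12625 probe sets on U95A, 19071 of 22283 on U133A, 15432 of 22645 on U133B and 9239 of 12607 spots. Probe sets with several symbols or none were left out of the gene tests, as were Y-linked genes, XIST and a few genes with common germline deletions. A gene was represented by its brightest probe set, and tested if its signal lay above the 40th percentile of its array on at least 2 of the 6 arrays. This left 8768 genes on U133A, 5888 on U95A and 7502 on U133B, and all 6739 two-colour genes were tested.

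Each comparison was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per cell type over all arrays of a type and moderated two-sided tests whose prior variance followed the signal for Affymetrix arrays. For two-colour arrays the mean ratio of a line was tested against 0, so HMEC there is a control channel without a spread of its own, and dye bias cannot be removed. Benjamini-Hochberg adjustment was made per array type and contrast, with a threshold of 0.05. A cell type whose signal lay under the 40th percentile of both its arrays was raised to that percentile, and the fold is then given as a lower bound. U133A was the main array type because it covers the most named genes.

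The 24 gene lists, a panel of 13 genes, the tests, and all alternatives but one were fixed before the data were examined. Lists were tested on U133A with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 24 lists of a contrast, and again with an estimated correlation. The genes named are, per contrast, the 10 with the largest fold in each direction, ranked after a cell type under the floor was raised to it, among those called on U133A and also, in the same direction, on U95A; the 3 in each direction called on U133B among genes without a U133A probe set; up to 4 called members of each list; and the panel. The two-colour and U95A values beside them come from separate fits.

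Alternatives were quantile normalisation, median centring, no filter, a filter at the 60th percentile, a floor at the 20th percentile, a variance prior without trend, the replicate number as a block, only the 2 groups compared, the mean over a gene's probe sets, every spot on its own, only called genes for the agreement between array types, and leaving out each array in turn. A fit of every probe set on its own was added after the data were seen. The steps were tested on simulated data. Values were drawn at random without differences between cell types, with the spreads of the real genes shuffled between them. Changes were then added to 50 genes per size in the arrays standing for HCC1954. For HCC1954 over HMEC on U133A, 20% of genes changed by 0.5 on the log2 scale, 80% of those changed by 1 and 100% of those changed by 2 were recovered, with 4 false calls among the 8768 genes. On simulated two-colour arrays 68% of changes of 1 and 88% of changes of 2 were recovered. Far fewer genes changed in the simulation than passed in the real data (4254 on U133A). These shares are therefore not the sensitivity of the tests reported. Figures were drawn with matplotlib 3.10.9.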

Results

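Transcript levels were measured in the breast cancer lines MDA-MB-436 and HCC1954 and in HMEC, the normal control, with 2 arrays per cell type on each of U133A, U95A and U133B and 2 two-colour arrays per line. The labels do not say whether the 2 arrays of a cell type came from separate cultures, so every p-value measures only the spread between these arrays, which may be technical, and their number limits the precision. Whether the same RNA served all array types is not labelled. On U133A the median log2 signal of the 6 arrays lay between 7.60 and 7.63, and the 40th percentile, used as the floor, between 7.12 and 7.16. Arrays of 1 cell type correlated at r = 0.994 or above across U133A probe sets, against at most 0.931 with another cell type. The 3' minus 5' signal of ACTB, a control for RNA quality, differed between the groups: on U133A it was -0.17 and 0.05 in HMEC and between -0.53 and -0.35 in the lines. The same control for GAPDH lay between -0.05 and 0.16 on these arrays. The 2 two-colour arrays correlated at r = 0.790 for MDA-MB-436 and 0.937 for HCC1954.

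MDA-MB-436 was compared with HMEC to find the transcripts that separate this line from normal mammary epithelium. KRT14, a keratin of basal and myoepithelial cells, was at least 147-fold lower in MDA-MB-436 (fitted log2 fold change -8.43, SE 0.122, adjusted p = 6.01e-14, n = 2 arrays per cell type). Its partner keratin KRT5 was 77.2-fold lower (log2 fold change -6.27, SE 0.117). The cysteine protease inhibitor CSTA was at least 85.0-fold lower, the serpin SERPINB5 at least 80.2-fold, KRT15 at least 64.9-fold and the ion transport regulator FXYD3 66.9-fold. On U95A the fold of FXYD3 was smaller (-3.43 on the log2 scale). The kallikrein proteases KLK10 and KLK7 were 56.7-fold and at least 51.8-fold lower. GPM6B, a membrane proteolipid, was at least 46.5-fold lower and the calcium-binding protein S100A2 45.3-fold lower. CDH1, the adhesion protein E-cadherin, was at least 26.2-fold lower.

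The complement proteases C1S and C1R rose, C1S 36.8-fold (log2 fold change 5.20, SE 0.145, adjusted p = 7.07e-12) and C1R 12.9-fold. The neuronal ubiquitin hydrolase UCHL1 rose 28.1-fold, and MAGEA4, a cancer-testis antigen, at least 23.4-fold. OASL and IFI44, both induced by interferon, rose 16.4-fold and 11.3-fold. The lipid droplet protein PLIN2 rose 13.9-fold, the glutathione transferase GSTM3 11.8-fold, DPYSL3, which acts in neuronal growth cones, 11.4-fold, and the purine synthesis enzyme PFAS 10.6-fold. On U95A the fold of GSTM3 was smaller, 1.30 on the log2 scale against 3.57 on U133A. Among U133B genes without a U133A probe set, the Notch ligand DNER rose 16.3-fold, the transcription factor ZIC2 at least 15.6-fold and the noncoding transcript PAX8-AS1 10.6-fold. C19orf33 was 67.2-fold lower there, the membrane protein MAL2 24.4-fold lower and the Wnt inhibitor APCDD1 at least 20.1-fold lower.

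The basal epithelial list fell, with 14 of 15 tested genes lower and none higher (median log2 fold change -4.30, or -4.01 with genes under the floor at their bound; adjusted p = 4.96e-13, and 0.0494 with an estimated correlation). In the list of epithelial junctions 19 of 23 genes fell and none rose (adjusted p = 6.63e-12), among them the desmosomal cadherin DSG3, at least 26.4-fold, the desmosome linker DSP, 16.4-fold, and the vesicle transport protein RAB25, at least 15.3-fold. Of the 24 lists 13 were called, 4 higher and 9 lower, and only these 2 kept their call with an estimated correlation. For the others the loss says little, since that version of the test has few degrees of freedom. Squamous differentiation fell, with 2 genes up and 16 down of 20 (adjusted p = 2.17e-07, but adjusted p = 0.0719 with an estimated correlation). The cornified envelope protein SPRR1B was at least 42.7-fold lower and the serpin SERPINB3 9.58-fold lower.

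Cell cycle genes rose, with 34 up and 4 down of 42 (adjusted p = 2.10e-06, but adjusted p = 0.254 with an estimated correlation). The mitotic transcription factor FOXM1 rose 9.55-fold, the centromere protein CENPF by 1.97 on the log2 scale and the mitotic kinase AURKB by 1.86. The interferon response rose, with 23 up and 2 down of 31 (adjusted p = 1.62e-05, but adjusted p = 0.10 with an estimated correlation). ISG15, a ubiquitin-like protein, rose by 3.02 on the log2 scale, whereas TRIM22, an antiviral ubiquitin ligase, was at least 18.4-fold lower. Cholesterol and fatty acid synthesis fell, with 1 up and 15 down of 21 (adjusted p = 1.62e-05, but adjusted p = 0.10 with an estimated correlation), and the sterol enzymes SC5D and HMGCS1 changed by -2.46 and -2.23 on the log2 scale. The p53 targets fell, with 2 up and 14 down of 19 (adjusted p = 3.31e-05, but adjusted p = 0.10 with an estimated correlation). The cyclin kinase inhibitor CDKN1A and the oxidoreductase TP53I3 both changed by -3.23.

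Myoepithelial and smooth muscle markers fell, with 1 up and 8 down of 11 (adjusted p = 0.000317, but adjusted p = 0.10 with an estimated correlation). The actin-binding protein TAGLN was at least 11.1-fold lower and the kinase MYLK changed by -3.49 on the log2 scale, with a smaller U95A fold for TAGLN (-1.94). Of 33 cancer-testis antigens listed 19 were on U133A, and only 7 passed the filter. Of these 7, 5 rose and none fell (adjusted p = 0.00112, but adjusted p = 0.108 with an estimated correlation), with PRAME at least 9.22-fold higher and MAGEA10 at least 6.15-fold. A gene under the floor in HMEC passes the filter only through a line where it is higher, so the lack of falls means little. The median of this list was 2.00 (log2), or 1.13 with 5 genes at their bound. Luminal epithelial genes fell, with 2 up and 9 down of 19 (adjusted p = 0.00218, but adjusted p = 0.130 with an estimated correlation), although the median was only -0.27 (-0.26 with 3 genes at their bound) and on U95A 0.01. KRT7, a keratin of simple epithelia, was at least 37.8-fold lower and the tetraspanin TSPAN1 9.38-fold lower. Targets of NF-kB rose, with 17 up and 3 down of 22 (adjusted p = 0.00253, but adjusted p = 0.317 with an estimated correlation), with the chemokine CXCL2 at 2.86 and the interleukin antagonist IL1RN at -3.50 on the log2 scale. The two-colour ratio of CXCL2 was near 0 (-0.11).

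Matrix proteases and their inhibitors fell, with 9 up and 16 down of 30 (adjusted p = 0.00547, but adjusted p = 0.115 with an estimated correlation), the kallikrein KLK5 at least 63.8-fold. Ribosomal proteins fell by a small amount, with 2 up and 13 down of 26 and a median of -0.19 (adjusted p = 0.00547, but adjusted p = 0.130 with an estimated correlation), and this call was lost under quantile normalisation (adjusted p = 0.251). Adjusted over the list alone, the counts of the 13 called lists were the same except for 18 genes up in the NF-kB list. The MHC class I list, with 9 up and 1 down of 17, was not called (adjusted p = 0.0561), and it was called without MDA-MB-436 replicate 1 (0.0365), HMEC replicate 1 (0.0155) or HMEC replicate 2 (0.0113), and under both other filters. Mesenchymal genes went both ways, 11 up and 8 down of 24 (adjusted p = 0.586), with the collagen COL6A2 at least 10.4-fold higher and the transcription factor SNAI2 at -3.98 on the log2 scale, although the two-colour ratio of SNAI2 was only -0.34.

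Not called either were the 17q12-q21 region around ERBB2 (3 up and 2 down of 15, adjusted p = 0.866), MHC class II (1 up and 3 down of 6, 0.561), hypoxia and glycolysis (9 up and 12 down of 29, 0.227), receptor tyrosine kinases and EGF-family ligands (6 up and 10 down of 20, 0.227), and immediate early genes (12 up and 9 down of 23, 0.561). In these lists the glycolytic enzyme ENO2 was at least 9.48-fold higher, the growth factor TGFA at least 14.9-fold lower and the phosphatase DUSP6 at least 23.8-fold lower. Markers of fibroblasts (1 up and 2 down of 7, adjusted p = 0.376), endothelium (1 up of 4, 0.586), leukocytes (2 down of 8, 0.282) and adipocytes (2 up of 5, 0.398) were not called. Adjusted over the list alone, 11 receptor tyrosine kinases and ligands and 1 leukocyte marker were lower. The adipocyte transcription factor PPARG rose at least 4.72-fold.

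In the panel, ERBB2 was 0.62 lower in MDA-MB-436 on the log2 scale (SE 0.118, adjusted p = 0.000517), a call lost with the mean over its 2 probe sets (-0.27), and its neighbour GRB7 was 0.66 lower. EGFR changed by -0.69 (adjusted p = 0.0055), a call lost without MDA-MB-436 replicate 2 (-0.38) or HMEC replicate 2 (-0.50), and only 2 of its 6 probe sets had this sign (mean -0.03). VIM, the intermediate filament vimentin, rose by 0.27 (adjusted p = 0.00993), lost without MDA-MB-436 replicate 2 (0.25) or HMEC replicate 2 (0.24) and with a variance prior without trend (adjusted p = 0.0634), and on U95A its fold was -0.16. The simple-epithelium keratins split, with KRT8 at -2.79 (U95A -1.35) and KRT18 at 0.69. The proliferation marker MKI67 rose by 0.68 (two-colour ratio 0.04) and the cell cycle inhibitor CDKN2A by 0.99. The oestrogen receptor ESR1 did not pass (0.09, adjusted p = 0.598), and the progesterone receptor PGR was under the filter and not tested on U133A. The signal of ESR1 lay between 7.20 and 7.41 on all 6 arrays, near the floor of 7.12 to 7.16, so its folds say little in any contrast.

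On U133A 5034 of 8768 genes passed, 2854 higher and 2180 lower in MDA-MB-436, and 900 and 773 of these changed at least 2-fold. The median SE was 0.133 on the log2 scale. Over all 8768 tested genes, 76.8% had both arrays of 1 cell type above both of the other, which chance gives for 33.3% of genes. U95A gave 1846 higher and 1605 lower of 5888 genes, U133B 1827 and 1506 of 7502, and the two-colour arrays 1430 and 1889 of 6739. The two-colour count of 3319 fell to 2204 without either HCC1954 array, since both lines share 1 estimate of the spread.

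**Figure D1:**
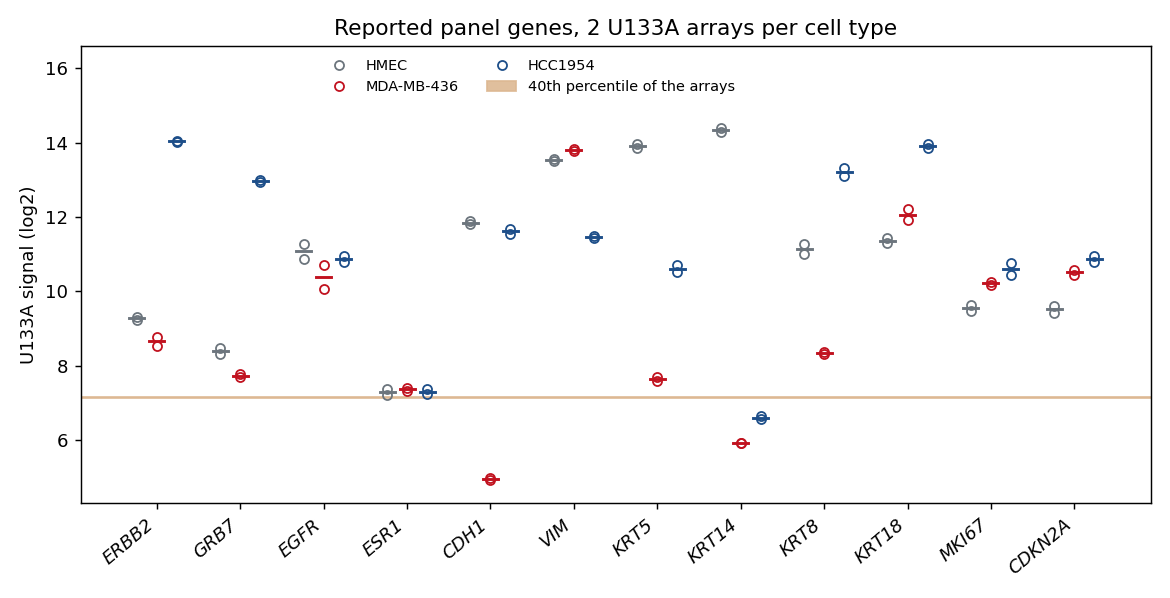
Log2 U133A signal of the 12 panel genes tested, with 1 open circle per array, a bar at the mean of the 2 arrays of each cell type, and a band at the 40th percentile of the arrays (7.12 to 7.16). ERBB2 and GRB7 stand highest in HCC1954, KRT14 and KRT5 in HMEC, and CDH1 lies under the band in MDA-MB-436 alone.

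HCC1954 was compared with HMEC for the same purpose. The receptor gene ERBB2 was 27.1-fold higher in HCC1954 (log2 fold change 4.76, SE 0.118, adjusted p = 4.41e-12, n = 2 arrays per cell type), and the two-colour arrays gave a log2 ratio of 4.92. The adaptor GRB7, which lies beside ERBB2, rose 23.9-fold. IFI27, an interferon-induced mitochondrial protein, rose at least 95.7-fold (fitted log2 fold change 6.67, SE 0.123, adjusted p = 3.15e-13), IFIT1, which binds viral RNA, 19.6-fold, BST2, which tethers virions, 15.6-fold, and IFI44L at least 14.5-fold. The kallikrein KLK6 rose 17-fold, the complement inhibitor CFI 15.4-fold, the phospholipase PLAAT4 15.3-fold and the checkpoint ATPase TRIP13 14.6-fold. On U133B the sphingolipid regulator ORMDL3, also a neighbour of ERBB2, rose 19.8-fold, the nucleotide kinase CMPK2 at least 17.8-fold and MYEOV 17.7-fold.

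KRT14 was at least 147-fold lower in HCC1954. LDHB, a lactate dehydrogenase subunit, was at least 77.2-fold lower (fitted log2 fold change -6.37, SE 0.109, adjusted p = 2.44e-13). The cyclin CCND2 was at least 54.4-fold lower, GPM6B 46.4-fold and SPRR1B 42.5-fold, each as a lower bound, and the U95A fold of CCND2 was smaller (-2.14 on the log2 scale). The other U95A probe set of CCND2 gave -6.37. KLK7 fell 37.0-fold, KLK10 36.0-fold, ADIRF, a regulator of adipogenesis, 32.4-fold, the serpin SERPINB7 30.4-fold and the matrix protein fibronectin, FN1, 26.6-fold. On U133B the cell adhesion protein EMB fell 24.9-fold, the arrestin family member ARRDC4 at least 23.1-fold and the interleukin receptor IL20RB at least 22-fold.

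The interferon response rose, with 29 up and 2 down of 31 (median log2 fold change 2.45, or 2.31 with 9 genes at their bound; adjusted p = 4.86e-17, but adjusted p = 0.0745 with an estimated correlation). Of the 24 lists 14 were called, 5 higher and 9 lower. None kept its call with an estimated correlation, where the lowest adjusted p of any list was 0.0745. That version of the test has few degrees of freedom, so the loss says little. Cell cycle genes rose, with 37 up and none down of 42 (adjusted p = 4.07e-12, but adjusted p = 0.126 with an estimated correlation), among them the kinase AURKA by 2.07 on the log2 scale, FOXM1 by 1.97 and the thymidine kinase TK1 by 1.70. In the 17q12-q21 region around ERBB2 11 of 15 genes rose and none fell (adjusted p = 5.11e-05, but adjusted p = 0.0745 with an estimated correlation), the gasdermin GSDMB at least 21.7-fold and the lipid transporter STARD3 12.8-fold. On U95A 8 of the 15 genes tested there rose and none fell. The median of this list was 0.335 on U95A, against 0.855 on U133A. MHC class I and antigen processing rose, with 13 up and 1 down of 17 (adjusted p = 5.72e-05, but adjusted p = 0.143 with an estimated correlation), with the immunoproteasome subunit PSMB9 10.1-fold higher and the peptide transporter TAP1 higher by 2.07 on the log2 scale. Luminal epithelial genes rose, with 12 up and 1 down of 19 (median 1.13, or 0.52 with 2 genes at their bound; adjusted p = 0.000144, but adjusted p = 0.110 with an estimated correlation). The disulphide isomerase AGR2 rose 13.0-fold, the transcription factor ELF3 8-fold and the mucin MUC1 by 2.45 on the log2 scale (U95A 1.39).

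The basal epithelial list fell, with 1 up and 13 down of 15 (median -2.18; adjusted p = 2.82e-09, but adjusted p = 0.0745 with an estimated correlation). KRT16 was at least 14.0-fold lower, S100A2 changed by -3.24 and KRT5 by -3.30 on the log2 scale. The p53 targets fell, with 2 up and 13 down of 19 (adjusted p = 6.03e-06, but adjusted p = 0.0745 with an estimated correlation), and the death receptors TNFRSF10B and FAS changed by -2.51 and -2.48. Myoepithelial and smooth muscle markers fell, with 8 down of 11 and none up (adjusted p = 1.14e-05, but adjusted p = 0.0745 with an estimated correlation), the actin-binding proteins CALD1 by a log2 fold change of -3.78 and TPM2 at least 9.29-fold. Matrix proteases fell, with 5 up and 17 down of 30 (adjusted p = 0.000118, but adjusted p = 0.0745 with an estimated correlation), including the urokinase PLAU, 13.5-fold. Mesenchymal genes fell, with 3 up and 11 down of 24 (adjusted p = 0.00186, but adjusted p = 0.110 with an estimated correlation), among them VIM at -2.07, the caveolin CAV1 at -2.21 and the matrix protein SPARC, at least 4.56-fold lower. The two-colour ratio of CAV1 was near 0 (-0.01).

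The other 4 calls were weaker. Ribosomal proteins fell, with 1 up and 10 down of 26 and a median of -0.15 (adjusted p = 0.00489, but adjusted p = 0.126 with an estimated correlation), and the call was lost under quantile normalisation (adjusted p = 0.318). Squamous differentiation fell, with 6 up and 11 down of 20 (adjusted p = 0.0120, but adjusted p = 0.126 with an estimated correlation), a call lost without HMEC replicate 2 (0.0932). CSTA changed by -3.81 on the log2 scale. Fibroblast markers fell, with 2 down of 7 (adjusted p = 0.0217, but adjusted p = 0.149 with an estimated correlation), a call lost without HMEC replicate 2 (0.111) and under both other filters, and their U95A median was 0.07. The fibroblast protease FAP changed by -3.13 on the log2 scale. Targets of NF-kB fell, with 5 up and 9 down of 22 (adjusted p = 0.0292, but adjusted p = 0.40 with an estimated correlation). Their median was only -0.11, and -0.02 on U95A. The call was lost without MDA-MB-436 replicate 1 or 2, although neither is in the groups compared. The interleukin IL1A was at least 11.6-fold lower and IL1B changed by -2.66.

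Adjusted over the list alone, 39 cell cycle genes, 1 myoepithelial marker and 6 NF-kB targets were higher and 18 matrix proteases and inhibitors lower, and the other counts of the called lists were the same. Lists not called were epithelial junctions (10 up and 7 down of 23, adjusted p = 0.734), cholesterol and fatty acid synthesis (9 up and 3 down of 21, 0.724), hypoxia and glycolysis (9 up and 11 down of 29, 0.173), cancer-testis antigens (3 up of 7, 0.117), receptor tyrosine kinases and ligands (5 up and 8 down of 20, 0.266), immediate early genes (7 up and 8 down of 23, 0.738) and MHC class II (1 up and 1 down of 6, 0.857). Endothelial (1 up of 4, 0.788), leukocyte (1 down of 8, 0.724) and adipocyte markers (1 up of 5, 0.738) were not called. The cancer-testis list was called under the 60th percentile filter (0.0444) and with the mean over probe sets (0.0415), and MAGEA6 rose at least 28.8-fold. Adjusted over the list alone, the hypoxia list had 10 up, the cholesterol list 4 down, the receptor list 6 up and the leukocyte list none down. Median, mean and test differed in sign for epithelial junctions (median 0.21, mean -0.27), immediate early genes (median 0.03, mean near 0 and negative) and endothelial markers (median -0.01, or 0.02 with 1 gene at its bound, mean 0.29). Among these lists DSG3 was at least 26.4-fold lower, the carbonic anhydrase CA12 19.9-fold lower, and the receptor FGFR4 4.58-fold higher.

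In the panel, KRT8 and KRT18 rose by 2.07 and 2.55 on the log2 scale, MKI67 by 1.06 and CDKN2A by 1.37, where U95A gave 0.53 for CDKN2A. CDH1 (-0.23, adjusted p = 0.143), EGFR (-0.21, adjusted p = 0.378) and ESR1 (0.02, adjusted p = 0.917) did not pass, and ESR1 lay near the floor in both cell types. On U133A 4254 of 8768 genes passed, 2514 higher and 1740 lower, with 673 and 577 changed at least 2-fold, and in 72.7% of the tested genes the arrays of the 2 cell types did not overlap. U95A gave 1418 higher and 1190 lower, U133B 1267 and 1411, and the two-colour arrays 1484 and 1562. The U133B count of 2678 was 1784 without HCC1954 replicate 1, and the two-colour count of 3046 was 1024 without HCC1954 replicate 1 and 729 without replicate 2.

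**Figure D2:**
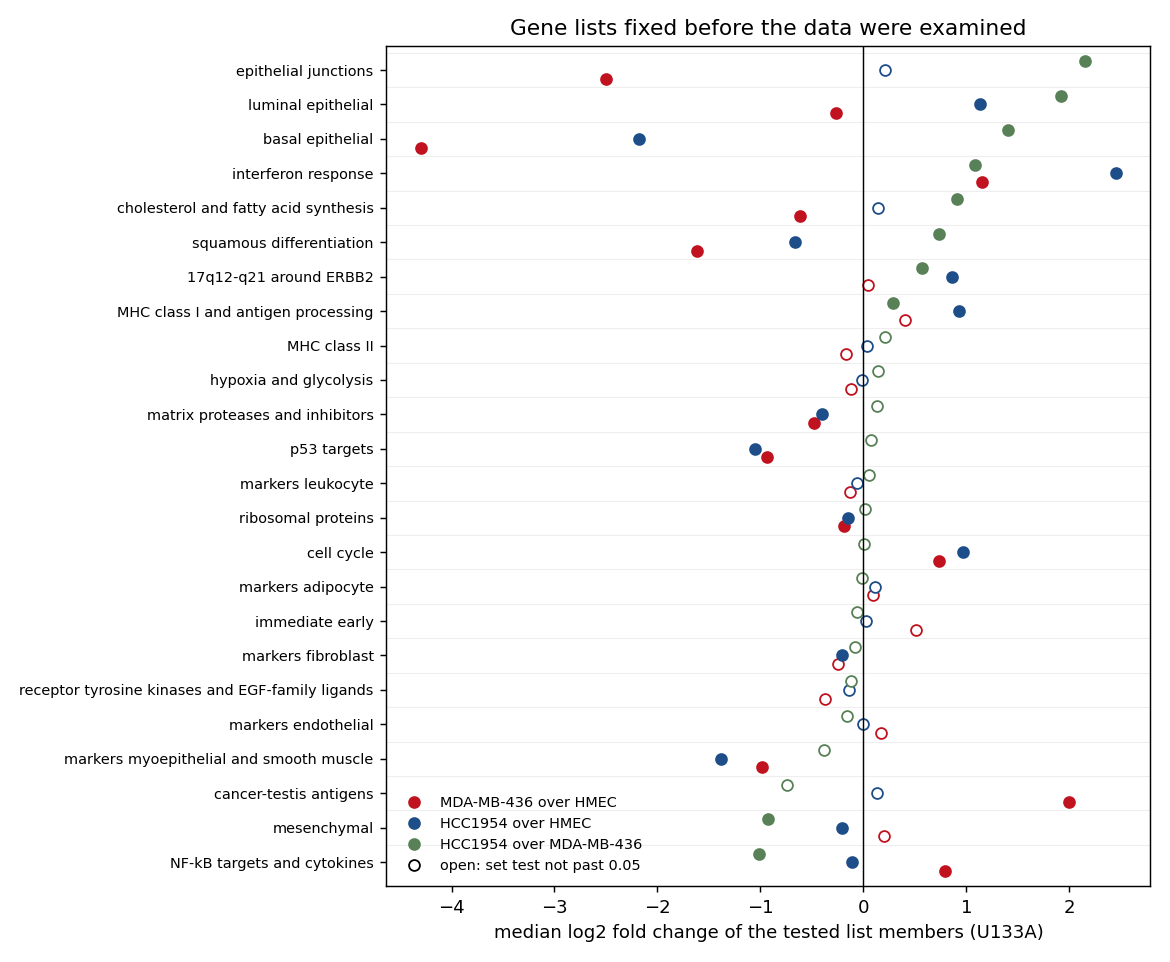
Median log2 fold change of the tested members of the 24 gene lists on U133A, with 1 point per list and contrast, filled where camera with a preset correlation passed 0.05. Basal epithelial genes lie at -4.30 in MDA-MB-436 and -2.18 in HCC1954 against HMEC, and the interferon response at 2.45 in HCC1954.

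The lines were compared directly to find what separates HCC1954 from MDA-MB-436. ERBB2 was 41.6-fold higher in HCC1954 (log2 fold change 5.38, SE 0.118, adjusted p = 8.72e-13, n = 2 arrays per line), with the same log2 difference of 5.38 on the two-colour arrays, and GRB7 was 37.8-fold higher. IFI27 was at least 96.3-fold higher. KRT15 was at least 85.6-fold higher (fitted log2 fold change 7.99, SE 0.149) and KRT7 at least 53.3-fold. KLK6 was 61.4-fold higher, RARRES1, a retinoid-induced carboxypeptidase inhibitor, 49.9-fold, FXYD3 43.6-fold and the calcium-binding protein S100P 35.3-fold. The matrix protein MGP was at least 32.8-fold higher, with a smaller U95A fold of 1.24 on the log2 scale, and that of FXYD3 was smaller too (2.17). On U133B the noncoding transcript UCA1 was 27.4-fold higher, ORMDL3 23.8-fold and the homeobox gene IRX2 at least 23.3-fold.

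LDHB was at least 111-fold lower in HCC1954 than in MDA-MB-436 (fitted log2 fold change -6.89, SE 0.109, adjusted p = 1.76e-13). The membrane-bound protein BASP1 was at least 64.4-fold lower, UCHL1 33.2-fold, MLLT11, a fusion partner in leukaemia, 27.9-fold, and the histone chaperone ANP32E at least 20.5-fold. MAGEA4 was at least 23.5-fold lower, although its two-colour difference was 0.40 on the log2 scale. TUSC3, a glycosylation subunit, was at least 19.0-fold lower, CA12 16.3-fold, the MAGE family member MAGED1 16.1-fold and the extracellular protein SRPX 15.7-fold, with smaller U95A folds for CA12 (-2.46) and SRPX (-2.40) on the log2 scale. The other U95A probe set of CA12 gave -4.735, against a fitted -4.03 on U133A. On U133B DNER was 31-fold lower, the lysosomal protein EPDR1 13.1-fold and the zinc finger gene ZNF655 at least 13.0-fold.

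Of the 24 lists 10 were called, 8 higher and 2 lower in HCC1954. None kept its call with an estimated correlation, where the lowest adjusted p of any list was 0.0828. With the few degrees of freedom of that version, the loss says little. Epithelial junctions were higher, with 18 up and none down of 23 (median 2.16, or 1.51 with 6 genes at their bound; adjusted p = 2.06e-09, but adjusted p = 0.0828 with an estimated correlation). The splicing regulator ESRP1 was 24.1-fold higher, CDH1 at least 22.3-fold and the adhesion protein EPCAM at least 19.6-fold. Luminal epithelial genes were higher, with 15 up and none down of 19 (median 1.92, or 1.71 with 5 genes at their bound; adjusted p = 9.18e-09, but adjusted p = 0.0828 with an estimated correlation), KRT8 28.9-fold (log2 fold change 4.86, and 2.70 on U95A) and AGR2 17.5-fold. The interferon response was higher, with 26 up and 2 down of 31 (adjusted p = 1.98e-08, but adjusted p = 0.0828 with an estimated correlation), the membrane protein IFITM1 30.7-fold and the oligoadenylate synthetase OAS2 6.89-fold. Basal epithelial genes were higher, with 14 up and 1 down of 15 (adjusted p = 5.17e-08, but adjusted p = 0.0828 with an estimated correlation), P-cadherin, CDH3, at least 18.3-fold and the stratifin SFN 11.4-fold. Cholesterol and fatty acid synthesis was higher, with 15 up and 1 down of 21 (adjusted p = 7.15e-06, but adjusted p = 0.0828 with an estimated correlation), HMGCS1 8.60-fold and the desaturase SCD by 2.06 on the log2 scale.

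Targets of NF-kB were lower, with 2 up and 17 down of 22 (median -1.01, or -0.98 with 5 genes at their bound; adjusted p = 9.19e-06, but adjusted p = 0.214 with an estimated correlation). IL1A was at least 15.6-fold lower, CXCL2 10.9-fold and IL1B 9.85-fold. Mesenchymal genes were lower, with 4 up and 13 down of 24 (adjusted p = 0.000442, but adjusted p = 0.0828 with an estimated correlation), among them COL6A2, at least 10.5-fold, and VIM at -2.34 on the log2 scale. Squamous differentiation was higher, with 14 up and 2 down of 20 (adjusted p = 0.000293, but adjusted p = 0.0828 with an estimated correlation), with the antimicrobial protein S100A7 at least 4.81-fold higher. The ERBB2 region was higher, with 9 up and 1 down of 15 (adjusted p = 0.000442, but adjusted p = 0.0828 with an estimated correlation), GSDMB at least 21.9-fold and the lipid remodelling enzyme PGAP3 14.1-fold. On U95A 7 of the 15 genes of this region tested there were up and 1 down, with a median of 0.135 against 0.57 on U133A. MHC class I and antigen processing was higher, with 10 up and none down of 17 (adjusted p = 0.0141, but adjusted p = 0.390 with an estimated correlation), including PSMB9 by 2.23 on the log2 scale. Adjusted over the list alone, 19 junction genes, 15 squamous genes and 10 genes of the ERBB2 region were higher, and the other counts of called lists were the same.

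Cell cycle genes were split between the lines, with 15 up, 9 down and 18 not passing (adjusted p = 0.376), the cyclin CCNE2 higher by 2.00 on the log2 scale and FOXM1 at -1.29. Cancer-testis antigens were split too (1 up and 4 down of 7, adjusted p = 0.0640), with MAGEA6 20.2-fold higher and MAGEA10 at least 6.17-fold lower. Not called either were the p53 targets (6 up and 4 down of 19, adjusted p = 0.663), hypoxia and glycolysis (9 up and 8 down of 29, 0.990), matrix proteases (13 up and 8 down of 30, 0.669), receptor tyrosine kinases and ligands (8 up and 8 down of 20, 0.990), immediate early genes (7 up and 8 down of 23, 0.657), ribosomal proteins (7 up and 6 down of 26, 0.894) and MHC class II (3 up of 6, 0.405). Markers of fibroblasts (2 down of 7, 0.293), myoepithelium (3 up and 5 down of 11, 0.550), endothelium (1 up and 1 down of 4, 0.902), leukocytes (2 up of 8, 0.657) and adipocytes (1 down of 5, 0.448) were not called, although the fibroblast list was under the 60th percentile filter (0.0455). Adjusted over the list alone, the hypoxia list had 10 up and 9 down. Median, mean and test differed in sign for the hypoxia list (median 0.14, mean -0.12), the receptor list (median -0.12, mean 0.01) and the endothelial list (median -0.16, or -0.12 with 1 gene at its bound, mean 0.05). The lysyl hydroxylase PLOD2 was 11.8-fold higher, KLK5 at least 51.8-fold, the protease CTSH 17.6-fold, the phosphatase DUSP1 8.03-fold lower and the growth factor EREG at least 9.06-fold lower.

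In the panel KRT5 and KRT18 were higher in HCC1954 by 2.98 and 1.86 on the log2 scale. KRT14 lay under the floor in both lines, so no fold is given. EGFR (0.48, adjusted p = 0.0421) lost its call without MDA-MB-436 replicate 2 (0.17), HCC1954 replicate 1 (0.41) or replicate 2 (0.56), and with the mean over its probe sets (0.20). Its call was also lost with the replicate number as a block (adjusted p = 0.0609), under quantile normalisation (0.0547), without a filter (0.0562), without the trend in the prior (0.0571) and with only the 2 groups (0.0506). MKI67 (0.38, adjusted p = 0.0296) lost it without MDA-MB-436 replicate 1 (0.42) or 2 (0.34) or HCC1954 replicate 1 (0.22) and with the mean over its probe sets (0.29), and its U95A fold was -0.35. CDKN2A (0.38, adjusted p = 0.0220) lost it without MDA-MB-436 replicate 2 (0.31) or HCC1954 replicate 2 (0.30) and under quantile normalisation (0.30), and reversed with the mean over its probe sets (-0.08) and on U95A (-0.72). ESR1, near the floor in both lines, did not pass (-0.07, adjusted p = 0.704).

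On U133A 4554 of 8768 genes passed between the lines, 2296 higher and 2258 lower in HCC1954, with 773 and 668 changed at least 2-fold, and in 73.4% of the tested genes the arrays of the lines did not overlap. U95A gave 1529 higher and 1433 lower, U133B 1385 and 1711, and the two-colour arrays 1164 and 969. The two-colour count of 2133 rests on the HCC1954 pair: it was 22 without HCC1954 replicate 2, 88 without HCC1954 replicate 1 and 1348 without MDA-MB-436 replicate 2.

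Many genes were called against HMEC in both lines. KRT14, KLK7, KLK10 and GPM6B were among the genes that fell most in both, the p53 target CDKN1A changed by -3.23 and -1.79 on the log2 scale, and FOXM1 rose by 3.26 and 1.97. On U133A 1452 genes were higher in both lines and 1075 lower in both, where the lists of calls, if independent, would overlap in 818 and 433. MDA-MB-436 was higher and HCC1954 lower for 235 genes, and the reverse held for 313, where the same reckoning gives 566 and 625. These reckoned overlaps leave out that the lines share the 2 HMEC arrays, which cannot be split into separate controls, so part of the excess may come from the shared controls. In 100 simulated data sets without any effect no gene was called in both lines, which is what data without effects must give. The covariance of the folds was 0.429, and 0.0112 in the simulated data, where the shared arrays add only chance. The correlation of the folds was 0.499, and 0.501 in the simulated data. Folds without effects that share a control group correlate near 0.5 by construction, so this likeness decides nothing. None of these values separates a change that both lines underwent from a state of the HMEC culture alone, which enters both folds alike.

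**Figure D3:**
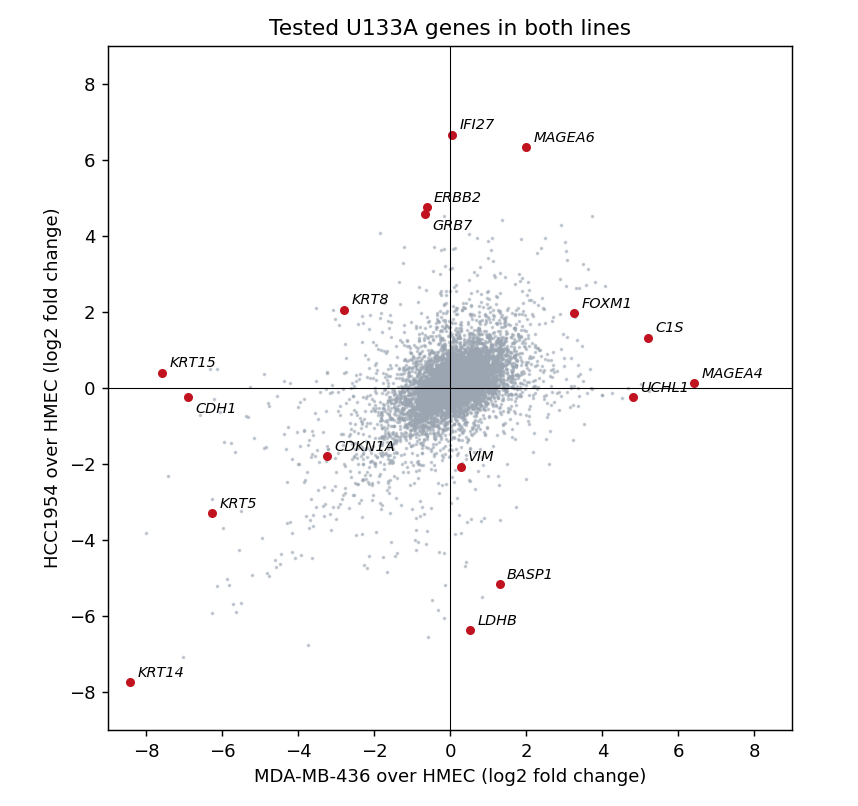
Log2 fold change of each of the 8768 tested U133A genes against HMEC, MDA-MB-436 on the horizontal and HCC1954 on the vertical axis, 1 grey point per gene with some of the genes named in the text in red. KRT14 lies far down in both lines, and ERBB2, GRB7 and IFI27 are high in HCC1954 alone.

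The array types were compared across genes, which are not independent replicates. The log2 folds of U133A and U95A correlated at r = 0.918 for MDA-MB-436 over HMEC, 0.914 for HCC1954 over HMEC and 0.925 between the lines over 5231 genes (Spearman's rho 0.905, 0.888 and 0.916). Genes called on both had the same sign in 99.3%, 99.5% and 99.8% of cases. With the two-colour arrays U133A correlated at 0.772, 0.794 and 0.769 over 4560 genes (rho 0.722, 0.735 and 0.731), and 100 of 1895, 72 of 1605 and 25 of 1388 genes called on both were opposite in sign. The direction of the two-colour ratios was read from the sign of this correlation. Only its size, and not its positive sign, therefore bears on the agreement. Genes that differed between U133A and U95A include GJA1, a gap junction protein, at -7.08 and -0.84 in HCC1954 over HMEC, and the elongation factor EEF1A2 at 4.52 and 0.23. These are fitted values, and with the group under the U133A floor raised to it the U133A folds are bounded at -4.60 for GJA1 and 3.90 for EEF1A2 on the log2 scale.

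**Figure D4:**
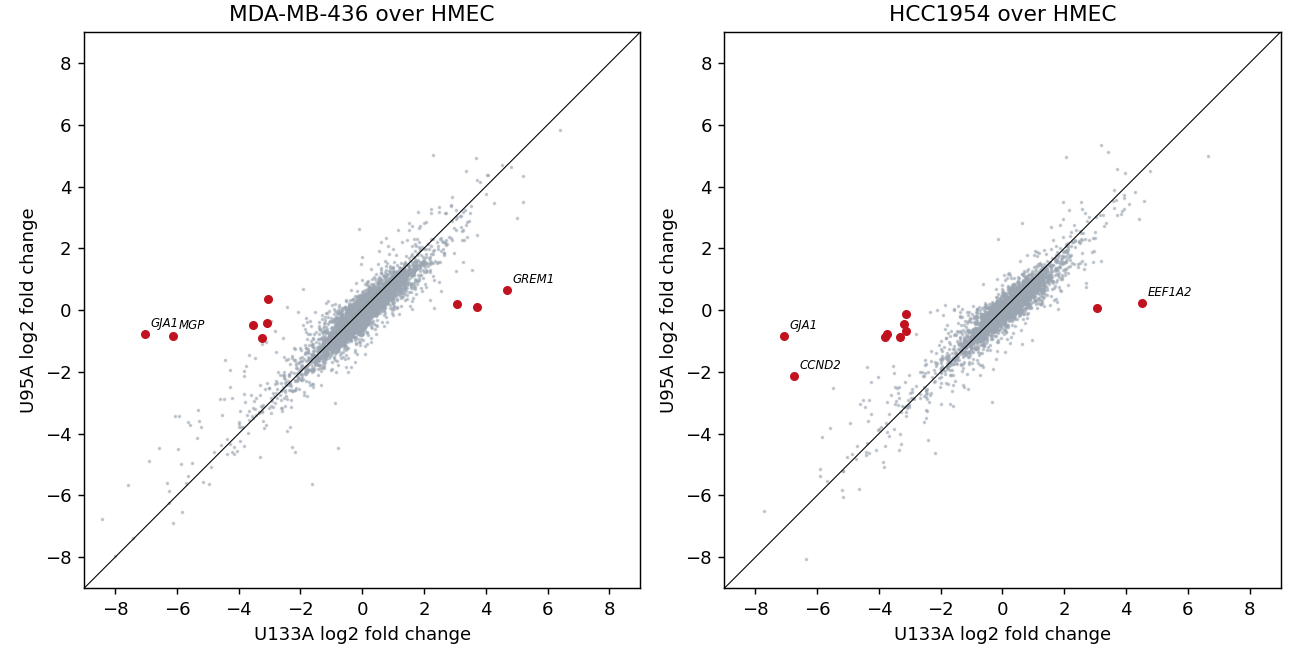
Log2 fold change on U95A against U133A for the 5231 genes tested on both, MDA-MB-436 over HMEC on the left and HCC1954 over HMEC on the right, with the line of equality. Red points mark genes with a fitted U133A fold of at least 3 (log2) and a much smaller U95A fold, such as GJA1 at -7.08 and -0.84 in HCC1954.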

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

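The fit of every probe set on its own, and the requirement of at least a 2-fold change against HMEC in both lines, were chosen after the data were seen. Groups of 2 arrays are too small to test a single array against its group.

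Some named genes moved in opposite directions from HMEC in the lines. Each was chosen for being at least 2-fold from HMEC both ways, so its fitted fold between the lines is at least 4-fold by construction, and a test of that difference adds nothing. Higher in HCC1954 and lower in MDA-MB-436 than in HMEC were KLK6, with a fitted log2 fold of HCC1954 over MDA-MB-436 of 5.94, RARRES1 (5.64), S100P (5.14), IFITM1 (4.94), KRT8 (4.86), EPCAM (4.83), ESRP1 (4.59), CTSH (4.14), S100A7 (3.52) and LCN2 (2.36). Lower in HCC1954 and higher in MDA-MB-436 were BASP1 (-6.47), EREG (-4.87), MLLT11 (-4.80) and S100A4 (-2.69). For 4 of these genes 1 line lay under the floor, so that the folds are only at least 64.4-fold for BASP1, 19.6-fold for EPCAM, 9.06-fold for EREG and 4.81-fold for S100A7, and their order by fitted size means little. With MDA-MB-436 raised to the floor S100A7 differed from HMEC by only -0.06 there, so its move in opposite directions rests on signal under the floor. KRT8, for example, changed by -2.79 in MDA-MB-436 and by 2.07 in HCC1954. The luminal epithelial list (median 1.92 between the lines) and the NF-kB list (median -1.01) were called in opposite directions in the lines and differed between them with camera's preset correlation, but not with an estimated correlation (adjusted p = 0.0828 and 0.214). The calls against HMEC were lost with it too, at 0.130 in MDA-MB-436 and 0.110 in HCC1954 for the luminal list. For the NF-kB list these adjusted p were 0.317 and 0.40, and its call in HCC1954 was lost on leaving out either MDA-MB-436 array. A call lost with an estimated correlation says little here, since that version of the test has few degrees of freedom. For S100A4 the U95A fold between the lines was smaller (-0.35). No technical explanation was tested for these genes. The groups differ by cell type, and the design cannot tell this apart from differences in donor, culture or RNA handling.

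Probe sets without a single gene name entered none of the gene comparisons. On U133B 407 of 3570 such probe sets were higher than in HMEC in MDA-MB-436 and 339 in HCC1954, each tested on its own, while 414 and 309 were lower. What they measure was not examined.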

How the results depend on the processing

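Every alternative but the fit of every probe set on its own, which was chosen after the data were seen, was fixed before the data were examined. Of the counts of genes and lists and the correlations between array types, 238 values under alternatives stayed within their limits and 29 did not. For correlations the limit was the SD over pairs of single arrays. For counts it was a wide factor: 2531 two-colour genes for HCC1954 over HMEC with the replicate number as a block stayed within it, against 3046. For list tests 1092 values kept their side of the threshold, 43 lost their call, 35 of them under an estimated correlation, and 8 gained one. For named genes 4701 values kept direction and call, 54 lost the call and 1 reversed: CDKN2A in HCC1954 over MDA-MB-436, at -0.0817 with the mean over its probe sets. The cause was not tested.

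In the order MDA-MB-436 over HMEC, HCC1954 over HMEC and HCC1954 over MDA-MB-436, the U133A counts with every probe set on its own were 8033, 6888 and 7202, and the U133B counts 5428, 4295 and 4937, since more units were tested. The two-colour counts with every spot on its own were 5845, 5467 and 3616, for the same reason. With an estimated correlation 2, 0 and 0 lists were called with limma's camera. That version of the test has few degrees of freedom, so the drop says little about the lists.

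With the replicate number as a block the two-colour count between the lines was 1368. The pairing is by number only: the deviations of arrays with the same number correlated between -0.27 and 0.34 across the Affymetrix types and at 0.00104 on the two-colour arrays. The block lowered the U133A counts to 4879, 4124 and 4425 and raised the U95A counts to 3603, 2757 and 3110, where same-number deviations of HCC1954 correlated at 0.253 with MDA-MB-436 and 0.337 with HMEC. Whether arrays with the same number shared a step was not labelled.

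Leaving out 1 array at a time, the U133A counts ranged from 4104 to 4964, 3278 to 4209 and 3698 to 4450, and the lone array left in a group is then assumed to vary like the others. HCC1954 over HMEC on U133B ranged from 1784, without HCC1954 replicate 1, to 2934. The two-colour counts ranged from 2204 to 3008, from 729, without HCC1954 replicate 2, to 3264 (1024 without HCC1954 replicate 1), and from 22, without HCC1954 replicate 2, to 2035 (88 without HCC1954 replicate 1, 1348 without MDA-MB-436 replicate 2). There the spread rests on the remaining pair, and the MDA-MB-436 pair correlated less than the HCC1954 pair.

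The correlation of U133A with U95A was 0.890, 0.882 and 0.902 without a filter, and 0.938 and 0.935 for the comparisons with HMEC under the 60th percentile filter. For HCC1954 over HMEC the correlation of U133A with the two-colour arrays was 0.771 without a filter, 0.823 under the 60th percentile filter and 0.804 over genes called in either table. The cause was not tested.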

Other observations

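The patterns were noticed in the data, and the 4 tests of their explanations were written down before those tests were run. The examples named were chosen after their values were seen.

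In some stretches of the chromosomes neighbouring genes moved together. In windows of 10 genes along the chromosomes, ordered by the RefSeq gene table of assembly GRCh38.p14, the median U133A log2 fold passed the limit that 1000 permutations of the genes gave (1.51, 1.28 and 1.39 for MDA-MB-436 over HMEC, HCC1954 over HMEC and between the lines) in 26 segments in all. In MDA-MB-436 all 23 genes from PYCR3 to RECQL4 were higher than in HMEC relative to the median of all genes (median 1.54), and all 11 from CCDC59 to EEA1 lower (median -1.37). In HCC1954 18 of 19 genes from KANK1 to CNTLN were higher (median 1.44), 13 of 14 from DLD to CAPZA2 were lower (median -1.40), and the segment from RPL19 to MSL1, which holds ERBB2, had a strongest window of 2.14, although only 8 of its 14 genes were higher. Signal shared between paralogs of a cluster would be lost on keeping 1 gene per symbol stem. Of the segments 92.31% (24 of 26, exact 95% confidence interval 74.9 to 99.1) stayed past the limit of the thinned genes. This argues against paralogs that share a stem as the cause for most of them. A window that began in a segment and ran past its end also counted as staying, so the share may be too high. The thinned limits were lower (1.465, 1.245 and 1.355 in the same order). Very short stems were not thinned, so the staying of the segment from S100A9 to S100A13 between the lines decides nothing. Paralogs with unlike names were not thinned either. The segments that did not stay were PIGN to CYB5A and CLEC11A to SIGLEC7 in MDA-MB-436. A shift of the whole segment predicts that U133B genes without a U133A probe set follow, and 75.15% of them (124 of 165, interval 67.8 to 81.5) had the segment's sign. Not every segment followed: 2 of 5 such genes did from GUCY1A1 to MSMO1 in MDA-MB-436, and 4 of 8 from PFDN4 to CTSZ in HCC1954. A shift of chromosome segments, as by a gain or loss of copies, may lie behind part of the pattern. This is left open, since the interval reaches below the share set beforehand. Copy number was not analysed here, neighbouring genes can share regulation, segments of different contrasts share arrays, and the intervals treat genes as independent. Some U133B genes were also counted more than once. The segment from RPL19 to MSL1, with 5 such genes, entered for HCC1954 over HMEC and again between the lines.

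Some large U133A folds were small on U95A. Of 364 pairs of gene and contrast with a fitted U133A log2 fold of at least 3 that were tested on U95A, 25, from 16 genes, had a U95A log2 fold smaller by a factor above 3, or of opposite sign. Where U95A held more than 1 probe set for the gene, another one showed at least 0.5 of the U133A log2 fold in 61.54% of the pairs (8 of 13, exact 95% interval 31.6 to 86.1). These pairs repeat genes across contrasts that share arrays: the 13 pairs come from 8 genes and the 8 recovered ones from 5. Counted by gene, a reckoning added after the result was seen, the exact 95% interval is 24.5 to 91.5. In HCC1954 over HMEC, for instance, another U95A probe set gave -6.78 for GJA1, -6.37 for CCND2 and 4.0 for EEF1A2. For these genes the brightest U95A probe set, which stood for the gene, differed from the other, but as a cause of the pattern this is left open, since by gene the interval reaches below the 25% set beforehand. The U95A level in the brighter group was also lower in these genes than in the other 339 pairs, by a median difference of -1.56 on the log2 scale (95% bootstrap interval -2.20 to -0.96, which treats pairs as independent too), but this cannot support low U95A signal as a cause: the 25 pairs were chosen for a small U95A fold, and a probe set that does not rise in the brighter group has a lower level there by construction. GREM1 (fitted 4.69 on U133A, at least 2.72 with HMEC raised to the floor, and 0.64 on U95A in MDA-MB-436 over HMEC) was not recovered by its other probe set, and MGP had only 1 on U95A and could not be tested this way. The cause of the pattern is left open, and no biological explanation was tested.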
